A study of Mus musculus with 2 samples.

How the data were processed

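H3K27ac HiChIP, which captures pairs of genomic segments held close together in chromatin that carries acetylated lysine 27 of histone H3 (a mark of active promoters and enhancers), was done on microglia of wild-type mouse brain. Per the labels' protocols, male C57BL/6J mice of 8 to 24 weeks had a transient occlusion of the middle cerebral artery (MCAO) of 60 minutes or sham surgery, and 200000 to 300000 CD45-intermediate CD11b-intermediate cells of a hemisphere were sorted, cross-linked chromatin was captured with 2 µg of antibody, and libraries were amplified with 14 PCR cycles. There was 1 library of sham-operated mice and 1 of mice at day 6 after MCAO. The number of animals behind each library is not given in the sources used here.

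The deposited files list called interactions, 1 list per library. HiC-Pro 3.1.0 and the mouse builds mm10 and GRCm38 are named in the submitters' processing notes. The interaction caller and its settings are not given in the sources used here; the column names are those that FitHiChIP writes. Per the file headers and the values, each deposited interaction joins a pair of 10 kb bins of the same chromosome, 20 kb to 2 Mb apart, both marked as lying in a peak. The deposited contact counts are whole, unscaled counts per pair of bins, and the deposited coverage of each anchor is a whole read count as well. Per the file headers, each anchor also has a bias value, which is a ratio: in every row it equalled the deposited coverage divided by 1 constant per library (1099 for sham and 799 for day 6), and it is called relative coverage here. The p-values and q-values deposited with each interaction are those of the authors' caller, per library, and the largest q-value was just under 0.001 in both lists. The expected contact count was the caller's probability times 1 constant per library, 3629250 for sham and 2258259 for day 6, and this constant was taken as the number of contacts that the caller modelled. The columns for mappability, GC content and restriction sites held 0 in every row and were not used. The total of sequenced or valid read pairs is not analysed here, so the sums of contacts below describe the called interactions and not the depth of a library.

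An interaction was counted as shared when both 10 kb anchors were the same bins in both lists. A number for comparison came from 100 circular shifts of one list along each chromosome, which do not keep the anchors in peaks. Genes were the 21883 protein-coding genes of the RefSeq annotation of GRCm38, which is the same assembly as mm10. That table gives no strand, so a transcription start could not be placed, and the planned measure of anchors at promoters was replaced, before any value per gene was computed, by anchors that overlap the span of a gene with 1 kb on each side. This span holds the transcription start but also the gene body. Neighbouring genes that lie in the same 10 kb bin share its interactions. Many genes named below have such neighbours, which are not all given there. For example, anchors of Canx also lie on Maml1, those of Ltc4s on Mgat4b and those of Aurkb on Borcs6. Those of Srebf1 also lie on Rai1 and Tom1l2, those of Tpi1 on Spsb2 and Usp5, and those of Apoe on Apoc1 and Tomm40.

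For each gene the contacts of all called interactions with an anchor on it were summed. The log2 ratio of day 6 over sham was taken after adding a prior of 5 contacts, scaled to the library, and dividing by the library's total contacts in called interactions. A gene with a log2 ratio of at least 1 was counted as having more contacts, and one with -1 or less as having fewer, if it had at least 3 interactions in 1 of the lists. More and fewer thus refer to shares of a library's called contacts, and a gene with equal counts in both lists can count as having fewer. With 1 library per group no test between the conditions was possible, no difference has a replicate check, and the fixed rule of size takes the place of a test. A gene without an interaction in a list had no contacts that passed the caller's threshold, and its level below the threshold is unknown, so interactions and contacts are given for such genes in place of a fold. Shares have exact (Clopper-Pearson) 95% intervals and single sums of contacts exact 95% Poisson intervals; both cover counting error only, and reads without molecular identifiers are not independent molecules. Intervals of a gene's log2 ratio come from the exact binomial interval of its contacts in both libraries, without the prior.

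Gene lists were fixed before the data were examined: homeostatic microglia, reparative and disease-associated microglia, scavenger and phagocytic receptors, inflammatory NF-kB response, interferon response, antigen presentation, growth factors and tissue repair, lysosome and lipid handling, cell cycle, transcription factors of microglia, glycolysis and hypoxia, and housekeeping. Marker lists of other cells that the sort could hold were fixed too, for monocytes and border macrophages, neutrophils, lymphocytes, endothelial and mural cells, neurons, the oligodendrocyte lineage and astrocytes. A member was measured if it had an interaction in either list. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size, matched on the mean level of both libraries in 20 classes, and a percentile up to 2.5 or from 97.5 was taken as standing apart. The percentile describes these libraries only. The genes named in the text were chosen by a rule fixed at the same time: of each gene list the 2 members with the highest and the 1 with the lowest log2 ratio among those with at least 3 interactions; always Igf1, Spp1, Apoe, Msr1, Zfp384, Yy1, P2ry12, Tmem119, Cx3cr1, Sall1, Csf1r and Spi1; the 5 genes with the highest and the 5 with the lowest log2 ratio of all; and of each marker list the member with the most contacts. Another gene of this rule is not reported here. Genes named outside this rule are marked as such.

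Correlations across the 19 autosomes used permutation tests (two-sided, 100000 permutations) with Benjamini-Hochberg adjustment over 9 relations. The gene and list measures were tested on simulated data drawn from the sham library, with 200 of 4182 genes changed 4-fold. Of the 100 raised and the 100 lowered genes 100% were recovered, and 0% of 3426 unchanged genes were called. Of 200 random lists of 30 genes 5% stood apart, which follows from setting random lists against random lists. The simulation held Poisson noise only, at the same interactions in both lists and without a calling threshold. It therefore gives no error rate for genes whose interactions are called in 1 list only. There were 22 alternatives, 13 planned and 9 chosen after seeing the data, and each result was recomputed under those that bear on it, which for the lists were 19. The planned ones changed the q-value limit, the contact minimum, the list lengths, the distance range, the overlap that counts as shared, the flank of the gene, the scaling, the prior, the unit and the minimum of interactions. The later ones used the gene ends only, scaling by modelled contacts or within chromosomes, relative coverage, matching within chromosomes or on gene length, members that share no interaction, genes with interactions in both lists, and fewer chromosomes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.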

Results

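The data compare the H3K27ac-anchored chromatin contacts of microglia from sham-operated mouse brain with those of microglia taken at day 6 after MCAO, a model of ischemic stroke. The sham list held 19061 called interactions between 18885 anchors, with 501608 contacts in all. The day 6 list held 42905 interactions between 32048 anchors, with 1074041 contacts. Each condition had 1 library.

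The day 6 list had 2.25 times as many interactions as the sham list. The extra interactions did not come with more contacts per interaction, since the median was 22 contacts in sham (interquartile range 16 to 31) and 20 at day 6 (16 to 29). The observed count was a median 4.21 times the count expected by the caller in sham and 4.16 times at day 6. The number of contacts that the caller modelled was lower at day 6, at 0.622 times that of sham, so that called interactions held 13.8% of the modelled contacts in sham and 47.6% at day 6. Very long interactions took a larger share at day 6: 1 Mb to 2 Mb made up 9.58% (95% interval 9.30 to 9.86%) of the day 6 list and 2.71% (2.49 to 2.95%) of the sham list. Those of 50 to 200 kb made up 38.0% (37.5 to 38.5%) at day 6 and 49.6% (48.9 to 50.3%) in sham. Those under 50 kb made up 16.7% (16.4 to 17.1%) and 12.8% (12.3 to 13.3%), and those of 200 kb to 1 Mb 35.7% and 34.9%. With the day 6 list shortened to the 19061 interactions of smallest q-value the ratio of the lists is 1 by construction.

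**Figure D1:**
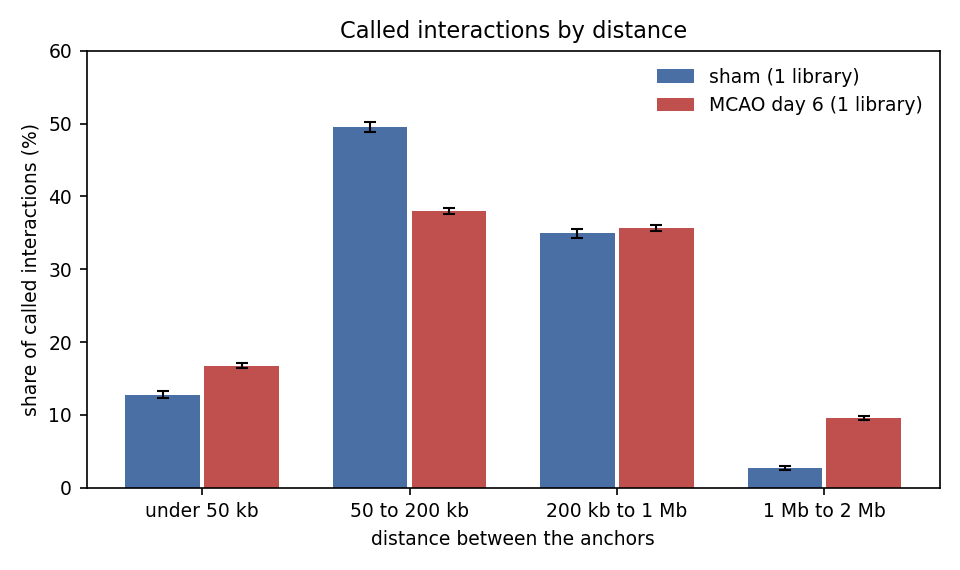
Share of called interactions (%, vertical axis) by the distance between their anchors (horizontal axis) in the sham and the day 6 library, with bars from 0 and exact 95% binomial intervals that cover counting error only. The class of 1 Mb to 2 Mb holds 2.71% of the sham list and 9.58% of the day 6 list.

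The lists had 4698 interactions in common, which is 24.6% (24.0 to 25.3%) of the sham list and 10.9% (10.7 to 11.2%) of the day 6 list. Circular shifts of one list gave a mean of 81.5 shared interactions (SD 10.9, range 49 to 106 over 100 shifts), and the observed number was 57.7 times this mean. The shifts do not keep anchors in peaks, whereas every anchor of both lists lies in a peak. A large excess therefore follows where peaks coincide, and it does not show that the same pairs of peaks were joined. With anchors allowed to differ by 1 bin, 57.4% (56.7 to 58.1%) of the sham interactions had a partner at day 6. Most sham interactions joined bins that were also anchors at day 6 (86.0% with both anchors), whereas 44.8% of the day 6 interactions had both anchors among those of sham. Strong interactions were shared more often: of the sham interactions with a -log10 q over 20, 68.8% (61.6 to 75.4%) were shared, and of those from 3 to 5, 18.7% (18.0 to 19.4%). Between the 16670 bins that were anchors in both lists, sham had 16387 interactions and day 6 had 19230, a ratio of 1.17 (1.149 to 1.198 by counting error). With lists of equal length the shared part was 15.2% of sham.

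The contacts of shared interactions had similar medians in both libraries. The median log2 ratio of day 6 over sham was 0.00 (interquartile range -0.37 to 0.34), with medians of 29 contacts in sham and 28 at day 6 and a Spearman rho of 0.704 across interactions, which are not independent replicates. With lists of equal length the median log2 ratio was 0.20. Coverage of the shared anchors had a rho of 0.891 and a median log2 ratio of -0.49. Coverage differed more from anchor to anchor at day 6, where the SD of log2 relative coverage was 0.727, than in sham, where it was 0.481.

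Genes lay at both ends of 65.2% (64.8 to 65.7%) of the day 6 interactions and of 59.4% (58.7 to 60.1%) of the sham interactions. With the gene ends only, in place of the whole span, these shares were 26.62% and 22.97%. Of all single bins, in a peak or not, 44.3% touch a protein-coding gene, which is no baseline for pairs of bins in peaks. Anchors with at least 5 interactions made up 14.5% (14.1 to 14.9%) of the day 6 anchors and 6.86% (6.50 to 7.23%) of the sham anchors, but 3.71% at day 6 with lists of equal length, so that the order of the libraries turned. Some of the busiest anchors are named here, chosen after their values were seen. In sham, the bin of Jun, a subunit of the AP-1 transcription factor, and that of Dusp6, a phosphatase of ERK, had 13 interactions each, and they had 13 and 16 at day 6. At day 6 the busiest bin, on chromosome 10 at Dot1l, Plekhj1 and Sf3a2, had 24 interactions against 1 in sham. The bins of Rela and Nfkb2, subunits of NF-kB, had 21 and 18 interactions at day 6 against 4 and 6 in sham. This was not particular to NF-kB genes, since the other busiest day 6 bins also had fewer interactions in sham. The bin of Etf1 and Hspa9 had 21 against 8, a bin of Mef2a 21 against 10 and that of Poldip3 18 against 3. A bin without a coding gene on chromosome 9 (123920001 to 123930000, mm10) had 22 interactions at day 6 and 13 in sham.

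In all, 13783 protein-coding genes had an interaction in either list, 9414 in sham and 13419 at day 6, with 9050 in both, 364 in sham alone and 4369 at day 6 alone. Of 9635 genes with at least 3 interactions in 1 list, 3768 had more contacts at day 6 by the rule of size, 995 had fewer and 4872 lay between. The rule compares shares of called contacts, and the total of called contacts was 2.14 times as large at day 6. Of those with more, 1982 had no interaction in the sham list. Among the 7629 genes with interactions in both lists, 1786 had more contacts and 971 fewer. The balance depended on the scaling. With scaling by shared interactions 6416 genes had more and 186 fewer, with scaling by modelled contacts 8091 and 79, and with lists of equal length 1874 and 1115. The median log2 ratio of all measured genes, 0.68 in the chosen scaling, was 1.69 with scaling by shared interactions and 2.22 with scaling by modelled contacts. The log2 ratios of single genes and the counts of members below use the chosen scaling, and only the medians of lists are set against matched genes. With scaling by modelled contacts, Atp6v0d2 (-1.42) was the only gene named below with interactions in both lists that still had fewer contacts by the rule of size. With gene ends only, Atp6v0d2 had no interaction in either list, so its difference rests on bins inside the gene.

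The genes with the highest and lowest log2 ratios had interactions in 1 list only. For these the size of the ratio rests on the prior, and the level below the caller's threshold in the other list is unknown. Canx, an endoplasmic reticulum chaperone, had 15 interactions with 629 contacts (95% Poisson interval 581 to 680) at day 6 and none in sham. Zbtb4 had 16 interactions with 549 contacts, Cd84, a receptor of the SLAM family, 20 with 468, Eno2 16 with 447 and 0610030E20Rik 14 with 479, again with none in sham. Without the flank Eno2 had 4 with 134. Alg12 and its neighbour Creld2 shared 3 sham interactions with 127 contacts (106 to 151) and had none at day 6. Ceacam1 had 4 sham interactions with 117 contacts, and Gm39566 and Tmem102, which share their anchors, had 3 with 99. Without the flank Alg12 and Gm39566 had no interaction in either list, and with a flank of 5 kb Creld2 had 1 interaction with 45 contacts and Tmem102 3 with 85 at day 6.

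Homeostatic microglia genes, which mark the resting state of these cells, had the lowest median of the 12 gene lists, a log2 ratio of -0.80 that was 0.30 with scaling by shared interactions and 0.97 with scaling by modelled contacts. Of 29 members with at least 3 interactions, 9 had fewer contacts at day 6, 2 had more and 18 were neither, but 1 had fewer and 8 more with scaling by shared interactions, and 0 and 13 with scaling by modelled contacts. P2ry12, the purinergic receptor by which microglia sense nucleotides, had 615 contacts (567 to 666) in sham and 594 (547 to 644) at day 6, in bins partly shared with Med12l and P2ry13. As a share of called contacts its log2 ratio was -1.14 (-1.31 to -0.98 by counting error), and with scaling by modelled contacts it was 0.63. Sall1, a transcription factor of microglial identity, had 283 contacts (251 to 318) against 254 (224 to 287), log2 -1.23 (-1.505 to -1.005), and 0.52 with scaling by modelled contacts. Cx3cr1, the fractalkine receptor, had 377 against 360, log2 -1.15 (-1.38 to -0.95), but -0.49 with lists of equal length and 0.61 with scaling by modelled contacts. The lowest member with at least 3 interactions, Olfml3, had 70 contacts against 28, log2 -2.17 but -0.71 with a flank of 5 kb. Cst3, named outside the rule, had 2 interactions with 126 contacts in sham and none at day 6. Tmem119 had 173 against 371 contacts, log2 0.00, and Csf1r, the receptor of the growth factor that microglia need, 137 against 402, log2 0.45 (0.17 to 0.75) but -0.41 with lists of equal length. The highest members were Sparc, with 1 interaction in sham and 11 at day 6 (log2 1.06, but 0.43 with lists of equal length), and Ltc4s, with none in sham and 4 at day 6.

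Matched random lists had a median of -0.27, and the homeostatic list was at percentile 0.04 among them. With scaling by shared interactions or modelled contacts the random lists were at 0.95 and 1.75, and the homeostatic list was at percentile 0 in both. The list no longer stood apart when only the ends of the genes were used (percentile 12.5, with 10 members with fewer contacts and 1 with more) or with the stricter q-value limit (percentile 3.48). Of all settings, gene ends only is the nearest to the planned measure of anchors at promoters. Over the 28 members with interactions in both lists the median was -0.80 at percentile 0.14. In relative coverage of anchors common to both lists it was 0.04, against 0.28 for matched lists, at percentile 0. The marker list of neurons had a median of -0.45 (percentile 5.65), which was 0.59 and 1.23 with these scalings.

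**Figure D2:**
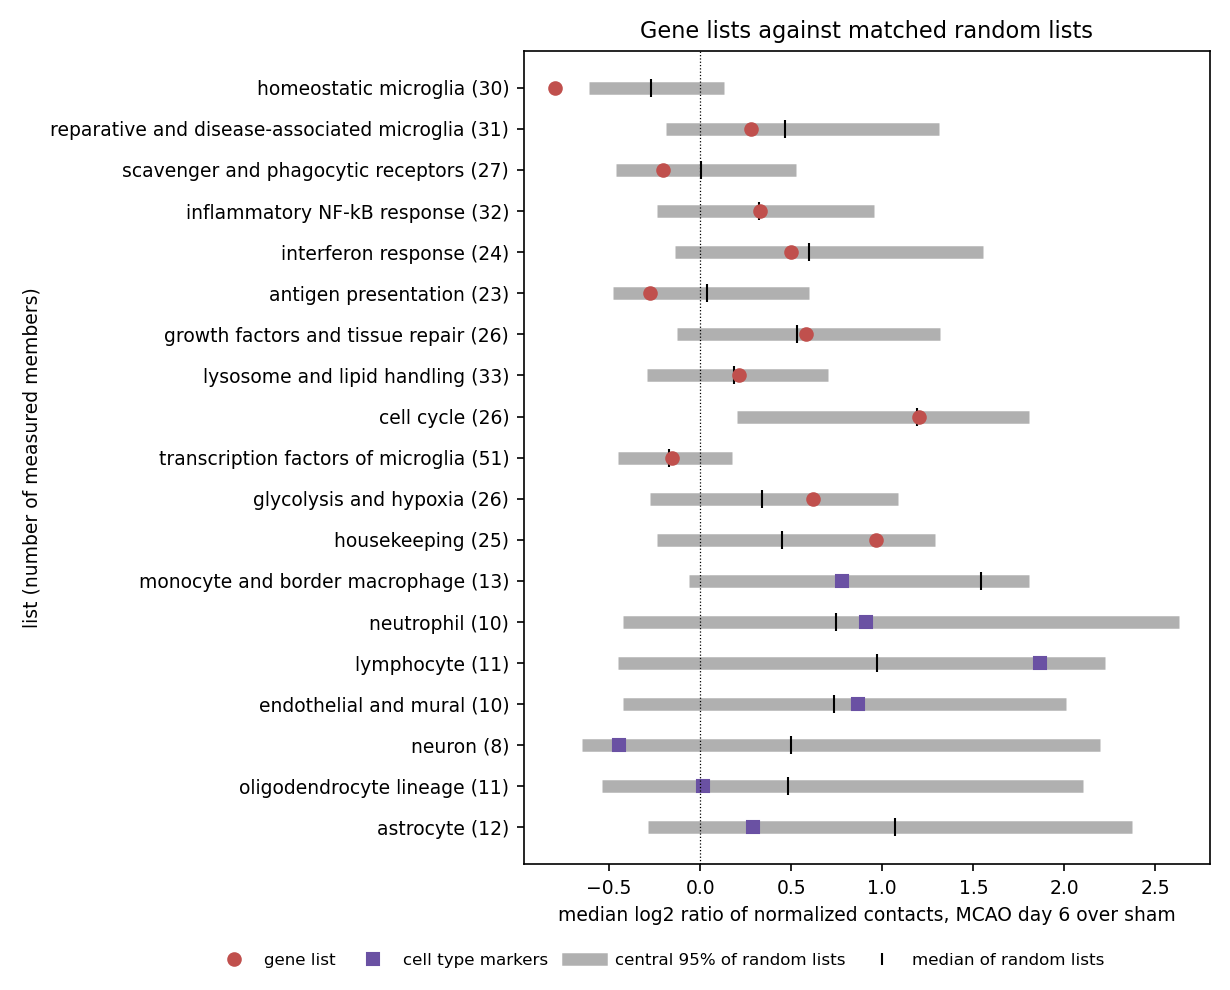
Median log2 ratio of normalized contacts, MCAO day 6 over sham (horizontal axis), of the measured members of each gene list (circles) and cell type marker list (squares), with the central 95% (grey bars) and the median (ticks) of 10000 matched random lists. The homeostatic list lies at -0.80, left of its grey bar, and its median turns to 0.30 or 0.97 with scaling by shared interactions or modelled contacts, where its random lists move to 0.95 and 1.75.

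Sall1 illustrates how the contacts of a homeostatic gene were placed. Its span on chromosome 8 (89027242 to 89044162, mm10) contacted distal bins without a coding gene in both lists, at 89380001 to 89410000 and at 89560001 to 89580000, as far as 550 kb away in sham and 530 kb at day 6. There were 14 interactions in sham and 11 at day 6, of which 6 were shared, with 119 contacts in sham and 122 at day 6. The shared part varied between homeostatic genes. P2ry12 shared 3 of 19 interactions in sham and 21 at day 6, and Cx3cr1 shared 4 of 8 and 11. Yy1, which encodes a zinc-finger factor that also binds at chromatin loops, had none in sham. At day 6 it had 5, with 193 contacts (167 to 222), from the bin at 108790001 to 108800000 on chromosome 12 to bins at Cyp46a1, Evl (2 bins) and Slc25a29 and to a bin without a coding gene 1620 kb away. Zfp384, another zinc-finger factor, had 188 contacts in sham and 392 at day 6, log2 -0.04 (-0.29 to 0.22), but 0.19 with lists of equal length.

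**Figure D3:**
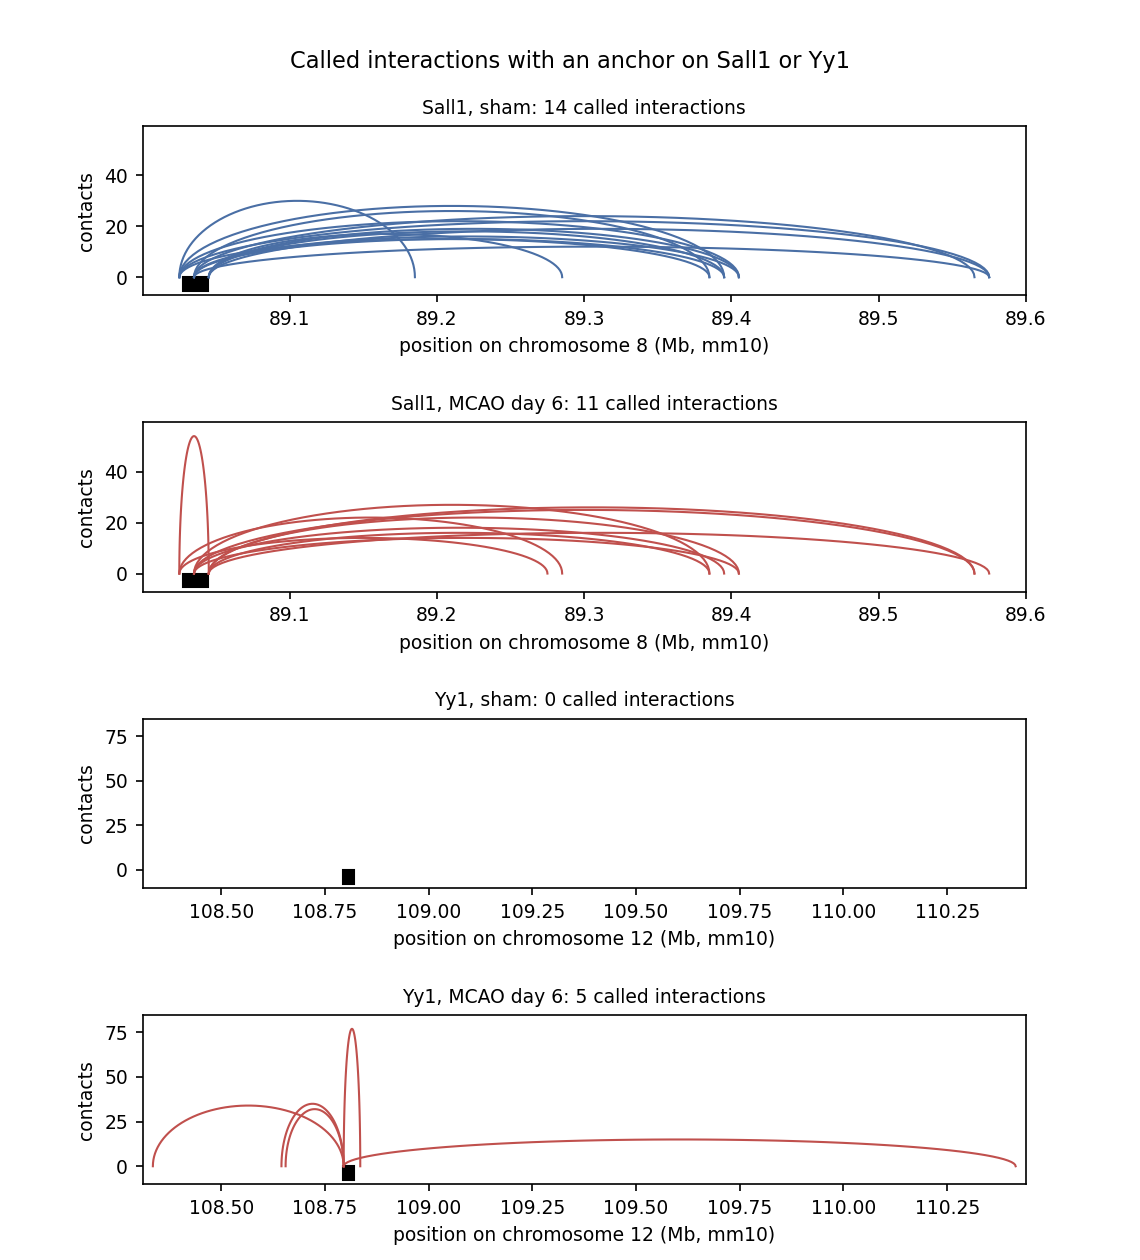
Called interactions with an anchor on Sall1 or Yy1 (black boxes) in each library, drawn as arcs between anchor centres along the chromosome (Mb, mm10) with the number of contacts as the height. Sall1 had 14 interactions in sham and 11 at day 6, and Yy1 had none in sham and 5 at day 6.

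Of the 31 measured reparative and disease-associated microglia genes, 10 had interactions at day 6 alone, against 4369 of all 13783 measured genes. Of 23 members with at least 3 interactions, 6 had more contacts, 1 had fewer and 16 were neither, with 15 more and 1 fewer by shared interactions and 19 and 0 by modelled contacts. Spp1, which encodes osteopontin, had 3 interactions with 49 contacts (36.3 to 64.8) at day 6 and none in sham. Igf1, a growth factor, had 1 interaction with 21 contacts (13 to 32.1) and none in sham. Cd63, a tetraspanin, had 5 with 106 contacts and Timp2, an inhibitor of metalloproteinases, 3 with 82, with none in sham. Anchors of Cd63 also lie on Bloc1s1, Gdf11 and Rdh5, and those of Timp2 on Cep295nl. With gene ends only Igf1 had none and Timp2 1 with 16 contacts at day 6, and with lists of equal length Spp1 had none. With a flank of 5 kb Timp2 had 9 with 249 contacts at day 6. Apoe had 102 contacts in sham and 198 at day 6, log2 -0.14 (-0.49 to 0.22), with no sham interaction left at the stricter q-value limit, and the lowest member was the protease gene Ctsl, with 145 and 53, log2 -2.41 (-3.03 to -2.09). The median of the list was 0.28 at percentile 29.9, and -0.02 at percentile 46.3 over members with interactions in both lists.

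Growth factor and tissue repair genes counted 6 members with more contacts, 1 with fewer and 12 neither (median 0.58, percentile 55.7), with 13 and 1 by shared interactions and 16 and 0 by modelled contacts. Tgfbi had 7 interactions with 170 contacts and Arg1, arginase 1, 4 with 76 at day 6, and neither had any in sham. Mmp14, a membrane metalloproteinase, had 130 contacts in sham and 39 at day 6, log2 -2.64 but -0.81 with a flank of 5 kb. Scavenger and phagocytic receptor genes counted 1 with more, 4 with fewer and 21 neither (median -0.21, percentile 22.7), but 11 with more and 1 with fewer by shared interactions and 19 and 0 by modelled contacts. The median of this list, like those of antigen presentation and of transcription factors below, was above 0 with scaling by shared interactions (0.87, 0.81 and 0.92) and by modelled contacts (1.54, 1.48 and 1.58). Megf10 had 3 interactions at day 6 (none with lists of equal length) and none in sham, Fcgr2b, an inhibitory Fc receptor, 12 at day 6 and 3 in sham (log2 0.57, but -0.83 with lists of equal length), and C1qb, of the complement component C1q, 1 and 3 (log2 -2.03, but -0.84 with a flank of 5 kb). The scavenger receptor gene Msr1 had 24 contacts in sham and 60 at day 6, log2 0.20 (-0.48 to 0.97), with no sham interaction left at the stricter q-value limit.

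In the NF-kB response list 7 members had more contacts, 4 fewer and 15 neither (median 0.33, percentile 50.8), but 16 had more and 0 fewer by shared interactions and 20 and 0 by modelled contacts. Tlr2, a sensor of bacterial lipoproteins, had 3 interactions with 172 contacts and Nos2, the inducible nitric oxide synthase, 7 with 140 at day 6, and neither had any in sham. Without the flank Nos2, which shares its anchors with Lgals9, had 1 interaction with 19 contacts. The chemokine gene Ccl7 had 89 contacts in sham and 52 at day 6, log2 -1.75. In the interferon response list 9 had more, 5 fewer and 8 neither (median 0.50, percentile 39.4), with Ifih1, a sensor of double-stranded RNA, and Rtp4 at 104 and 98 contacts at day 6 and none in sham, and Dhx58 at 205 and 109 contacts, log2 -1.94 but -0.22 with scaling by modelled contacts. With gene ends only Ifih1 had 1 interaction with 65 contacts. The counts of the interferon list were 14 with more and 0 with fewer by shared interactions, 17 and 0 by modelled contacts, and 3 and 5 with lists of equal length. In the antigen presentation list 4 had more, 2 fewer and 17 neither (median -0.28, percentile 12.9), but 9 had more and 1 fewer by shared interactions and 20 and 0 by modelled contacts. The class II gene H2-Aa had 67 contacts (none with lists of equal length) and H2-Q7 had 93 at day 6 and none in sham, whereas H2-DMb1 had 252 in sham and 118 at day 6, log2 -2.13.

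Metabolic and general lists lay within the range of their random lists. Lysosome and lipid handling genes counted 8 with more contacts, 6 with fewer and 17 neither (median 0.21, percentile 53.5), but 16 and 3 with more and fewer by shared interactions and 25 and 1 by modelled contacts. Srebf1, a regulator of lipid synthesis, had 11 interactions and Soat1, which esterifies cholesterol, 9 at day 6 (4 with gene ends only) and none in sham. Atp6v0d2, a subunit of the vacuolar proton pump, had 2 at day 6 and 10 in sham (log2 -3.10), but none in either list with gene ends only. Glycolysis and hypoxia genes counted 9, 3 and 11 (median 0.62, percentile 79.5), but 16 and 0 by shared interactions and 19 and 0 by modelled contacts. The glycolytic enzyme genes Eno1 and Tpi1 had 8 and 7 interactions at day 6 and none in sham, but Eno1 had 2 sham interactions with 28 contacts with a flank of 5 kb and Tpi1 had 4 at day 6 without the flank. Hmox1, heme oxygenase 1, had 158 contacts in sham and 109 at day 6, log2 -1.58 but 0.14 with scaling by modelled contacts. Cell cycle genes counted 6, 2 and 7 (median 1.201, percentile 50.8), and 10 and 0 or 11 and 0 with more and fewer in these scalings. They included Aurkb and Ccnb1 at 260 and 132 contacts at day 6 and none in sham, and Ccnd2 at 145 and 72, log2 -2.01 but -0.50 with gene ends only. Transcription factors of microglia counted 10, 9 and 31 (median -0.15, percentile 55.8), but 22 and 0 with more and fewer by shared interactions and 35 and 0 by modelled contacts. Besides Yy1, Egr3 had 132 contacts at day 6 and none in sham, and Etv5 had 238 in sham and 135 at day 6, log2 -1.86 but -0.64 without a flank. Spi1, which encodes PU.1, had 443 and 889 contacts, log2 -0.09 (-0.26 to 0.07), but 1.04 with gene ends only. Housekeeping genes counted 9, 4 and 9 (median 0.96, percentile 88.9), but 15 and 1 with more and fewer by shared interactions, 15 and 0 by modelled contacts and 3 and 5 with lists of equal length. They included Vcp and Ppia at 164 and 97 contacts at day 6 and none in sham, and Tubb5 at 229 and 105, log2 -2.15 but -0.77 with a flank of 5 kb.

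With lists of equal length the members with more and fewer contacts were 6 and 9 of the transcription factors, 4 and 2 of glycolysis and hypoxia, 3 and 2 of the cell cycle and 6 and 6 of lysosome and lipid handling. They were 0 and 9 of the homeostatic list, 4 and 1 of the reparative, 6 and 1 of the growth factor, 0 and 5 of the scavenger, 4 and 3 of the NF-kB and 3 and 2 of the antigen presentation list. Shortening the day 6 list leaves out day 6 interactions by construction. Of the 29 named genes with interactions at day 6 alone, 3 (Spp1, Megf10 and H2-Aa) then had none, 15 had over 1.5 times fewer contacts and 11 stayed within 1.5 times. Among the 15, Tlr2 had 53 contacts, Nos2 68, Rtp4 55, H2-Q7 28, Tgfbi 102, Timp2 51 and Ltc4s 149, Srebf1 had 98, Soat1 58, Ccnb1 81, Egr3 42, Vcp 70 and Ppia 52, and Cd84 had 280 and Eno2 268. Olfml3, C1qb and Dhx58, with interactions in both full lists, had none at day 6.

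Markers of other cell types rested on few genes, from 8 to 13 measured members a list, and no list stood apart. The monocyte and border macrophage list had a median of 0.78 (percentile 14.5), the neutrophil list 0.91 (58.9), the lymphocyte list 1.86 (75.5), the endothelial and mural list 0.86 (57.7), the neuron list -0.45 (5.65), the oligodendrocyte list 0.01 (20.3) and the astrocyte list 0.29 (15.4). By the rule of size 0, 4, 2, 2, 3, 1 and 2 members had more contacts and 1, 1, 0, 0, 3, 2 and 0 had fewer, in the same order. By shared interactions 2, 6, 4, 6, 4, 6 and 3 had more and 0, 1, 0, 0, 1, 0 and 0 fewer, and by modelled contacts 3, 8, 7, 7, 4, 6 and 7 had more and 0 fewer. With lists of equal length 1, 1, 1, 3, 0, 0 and 1 had more and 2, 2, 0, 1, 4, 2 and 0 fewer. The neuron list was at percentile 0.11 over the 6 members with interactions in both lists, but at 50.2 with gene ends only. The neuronal kinase gene Camk2a had 12 interactions in sham and 6 at day 6, log2 -1.96 (-2.32 to -1.71). The marker genes with the most contacts in the other lists were Ahnak (290 and 452 contacts in sham and at day 6), Csf3r (63 and 205), Ets1 (253 and 790), Slc2a1 (98 and 319), Mbp (189 and 432) and Slc1a3 (168 and 261). With gene ends only Ahnak had 220 and 344, Ets1 0 and 23, Slc2a1 24 and 211 and Mbp 70 and 96, while Csf3r was unchanged. Slc1a3 then had 87 and 225, and its log2 ratio turned from -0.45 to 0.26. That of Csf3r was 0.58, but 3.89 at the stricter q-value limit. Ets1 and Slc2a1 are also used by microglia or other cells and do not single out a type.

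Coverage of anchors differed between chromosomes in both libraries. The median relative coverage was highest on chromosome 11, at 1.27 in sham and 1.19 at day 6. It was lowest among the autosomes on chromosome 8 in sham (0.951) and on chromosome 6 at day 6 (0.809). Across the 19 autosomes it fell with the alphabetical rank of the chromosome's name (1, 10, 11 up to 9), with Pearson's r of -0.89 and Spearman's rho of -0.92 in sham and -0.85 and -0.89 at day 6. The permutation p was 1e-05 for each, the smallest that 100000 permutations give, and 4.5e-05 after Benjamini-Hochberg adjustment over 9 relations. Without the 2 chromosomes farthest from the median rank, r was -0.86 and -0.81. The rank correlation with the chromosome number was near 0 (rho 0.04 and 0.10, permutation p 0.860 and 0.678), and that with the density of coding genes was small (rho -0.19 and -0.05, permutation p 0.441 and 0.831). The ratio of day 6 to sham interactions also followed alphabetical rank (r -0.59, permutation p 0.00645, adjusted 0.0193, and rho -0.56, permutation p 0.0130, adjusted 0.0391). Without the 2 chromosomes r was -0.50. The ratio was 3.07 on chromosome 11, where Canx and Zbtb4 lie, 1.89 on chromosome 9 and 1.21 on chromosome X.

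**Figure D4:**
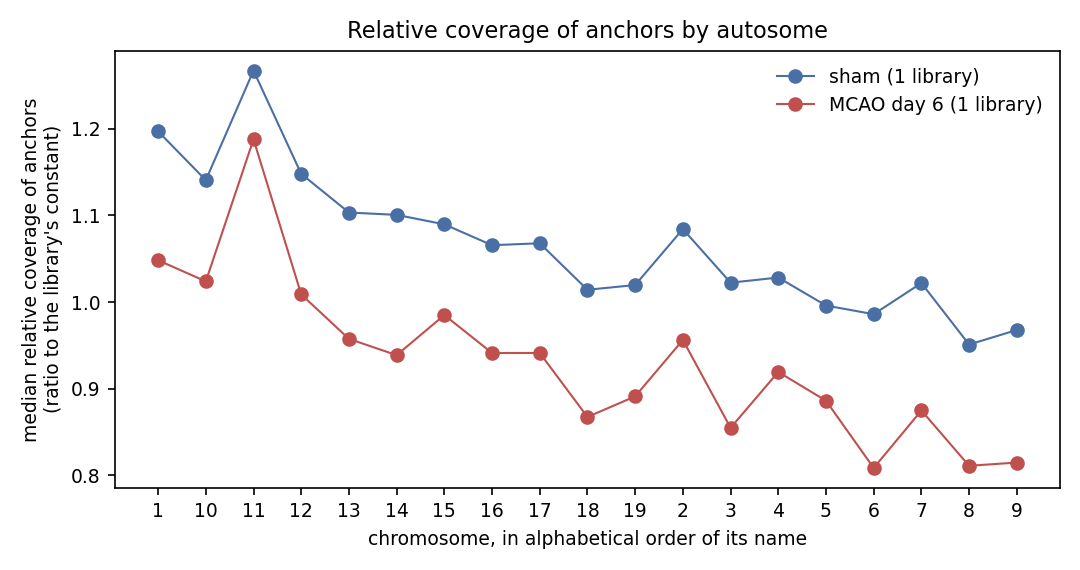
Median relative coverage of anchors (vertical axis, ratio to the library's constant, axis not from 0) for each autosome in the alphabetical order of its name (horizontal axis), 1 point per chromosome and library. Values fall from chromosomes 1 to 12 on the left to 9 on the right in both libraries, with chromosome 11 highest at 1.27 and 1.19.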

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

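The alternatives using gene ends only, scaling by modelled contacts, both-list genes, relative coverage, chromosome or gene-length matching, members sharing no interaction, scaling within chromosomes and fewer chromosomes were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The homeostatic list stood apart, below its random lists, under 17 of 19 alternatives, at percentiles from 0 to 12.5 over all 19. These alternatives reuse the same 2 libraries and are not independent checks. Several of them could hardly change the call. Scaling by shared interactions or modelled contacts moves genes with interactions in both lists by similar amounts. The other priors and the higher contact minimum alter the members little (percentile 0.05 and 0.02 with priors of 2 and 20, and 0.06 with the contact minimum). Gene ends only, although added later, is the setting nearest to the planned measure of anchors at promoters, and there the list did not stand apart. Its median minus that of all genes was -1.93 (percentile 3.48) with the stricter q-value limit and -1.23 (percentile 12.5) with gene ends only, where 0 of the 12 gene lists stood apart. The other 11 gene lists stood apart under none of these alternatives. For the marker lists, the neuron list was lower than its random lists under 5 alternatives, and the median of the neutrophil list minus that of all genes was -0.34 (percentile 1.75) in relative coverage. The cause was not tested.

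With the stricter limit the shared part was 23.7%, the share with genes at both ends in sham 57.8%, and anchors of at least 5 interactions 3.75% in sham and 8.17% at day 6. With equal lengths the ratio of interactions was 1, the shared part 15.2%, the log2 ratio of shared contacts 0.20, the gene share at day 6 65.8%, busy anchors at day 6 3.71% and genes with more contacts 1874. The shorter list and the smaller q-values follow from the setting. Up to 1 Mb, busy anchors at day 6 were 12.7%. Within 1 bin the shared part was 57.4% and the log2 ratio 0.051. Genes at both ends were 56.9% and 62.8% without a flank, 66.5% and 71.3% with 5 kb and 22.97% and 26.62% with gene ends, in sham and at day 6. Genes with more and fewer contacts numbered 6416 and 186 with scaling by shared interactions, 8091 and 79 by modelled contacts, 6173 and 1753 with a minimum of 1 interaction, and 1838 and 460 with 6. Those with more numbered 1786 among genes in both lists.

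Of 1027 values of named genes under alternatives, 927 kept their direction and side of the rule. Another 42 lost the call, 22 gained one, 32 of uncalled genes changed sign and 4 called ones reversed. Many of these outcomes were fixed by the settings, so the 927 do not measure robustness. Changing the minimum of interactions leaves a gene's log2 ratio as it was. Another prior or library scaling cannot turn the sign for genes with interactions in 1 list only, which include 29 named genes at day 6 alone. With modelled contacts Hmox1 was 0.14, P2ry12 0.63, Cx3cr1 0.61 and Sall1 0.52, where the scaling moved the median of measured genes by 1.53. With numbers of interactions in place of contacts P2ry12 (-0.98), Cx3cr1 (-0.65), Ccl7 (-0.89), Etv5 (-0.83) and Hmox1 (-0.70) lost the call. A gene with 1 interaction, such as Igf1 with 21 contacts, has a wide counting interval, and absence from a list sets no upper limit on contacts.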

Other observations

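The comparison with lists of equal length was planned, though how it bears on the homeostatic list was set down after its value was seen; the other tests in this part were chosen after the patterns were seen, and of these only the tests of gene length and of gene density had not been run when their outcomes were set down. Gene families that share the start of their symbol were scanned as well, with 82 families of at least 15 measured members set against 2000 matched random lists each. Of these, 1 stood apart at the low end and 2 at the high end, against the 4.1 that chance gives. Olfactory receptor genes (Olfr, 30 measured, on 13 chromosomes) had a median log2 ratio of -0.07, which was 0.87 with scaling by shared interactions and 1.46 by modelled contacts, and lay below matched lists in each (percentile 0, 0.15 and 1.05, and 0.1 with matching within chromosomes). Ube genes, which encode enzymes of ubiquitin conjugation, had a median of 1.64 (36 measured), against 0.67, at percentile 99.0, with 99.4 within chromosomes and 99.95 under both other scalings. Mapk genes, grouped by the start of their symbol and not all necessarily kinases, had a median of 1.91 (16 measured) at percentile 97.8, but 95.1 within chromosomes and 95.2 with scaling by modelled contacts. Neighbouring members of a family can share interactions, which a random list does not copy.

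The first pattern is the larger number of interactions at day 6. More contacts behind the day 6 list are argued against by the modelled contacts, as read from the caller's columns, which were 0.622 times those of sham, and by the deposited coverage of shared anchors, which was lower at day 6 (median log2 -0.49). A longer list of peaks may have added interactions and stays open: between bins that were anchors in both lists the ratio was 1.17 against 2.25 over the whole lists, but these bins were chosen by their called interactions, and the peak lists are not analysed here. The same q-value limit also let in larger p-values of the caller at day 6 (largest 9.9e-05, against 2.2e-05 in sham). The number of pairs that were tested is not given in the sources used here, so these p-values do not settle the question. A lower contrast of coverage between bins in the sham library (SD of log2 relative coverage 0.481, against 0.727 at day 6, over anchors of both lists) stays open and was not tested, since coverage of bins without called interactions is not analysed here. An effect of stroke on the cells stays open and untested, because each condition has 1 library.

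The second pattern is the low position of the homeostatic list. It was not removed by lists of equal length (percentile 0.23) or by matching on gene length (percentile 0.1), which argues against either as the whole cause. The list did not stand apart with gene ends only (percentile 12.5) or with the stricter q-value limit (percentile 3.48). Its call therefore depends on counting bins inside genes and on the q-value limit, and the reason was not tested. Cells of other types could lower the share of microglial contacts: the CD45-intermediate CD11b-intermediate gate would remove most neurons, other glia, endothelial cells and lymphocytes, and monocytes or border macrophages (list at percentile 14.5) are those nearest to it. They cannot be told apart from a difference within microglia, because the marker lists hold only 5 to 9 members with at least 3 interactions, and the highest list, that of lymphocytes, was at percentile 75.5. A smaller share of called contacts at homeostatic genes after stroke is one hypothesis, and the contacts summed over the members were 12927 in sham and 16468 at day 6.

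The third pattern is the fall of coverage with the alphabetical order of the chromosomes. Gene density does not account for it, since density was itself little related to coverage (Spearman's rho -0.19 in sham and -0.05 at day 6). Removing density could therefore change little, and the rank correlation left was -0.93 in sham and -0.94 at day 6 (permutation p 1e-05 for each, the smallest possible). An effect of the order of chromosomes in the processing was not tested, since the correlation that would show it is the pattern itself, and no biological explanation was tested. Matching within chromosomes left the homeostatic list at percentile 0.04.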
